A study of Mus musculus with 16 samples.

How the data were processed

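Livers of male mice on a chow diet were profiled on 2-colour expression arrays, 1 array column per mouse. The series holds 8 mice heterozygous for a targeted Lpl allele (Lpl+/-) and 8 wild type littermates, and every mouse was compared with the same pool of liver RNA from 9 wild type mice. Per the labels' protocols, RNA was extracted on spin columns with DNase and labelled by an automated aminoallyl method, with Cy3 in channel 1 and Cy5 in channel 2. Per the design text, dyes were swapped, but how the swapped hybridizations were joined into 1 column per mouse is not given in the sources used here, nor are the scanner, the background correction or the normalization.

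The deposited values are log ratios of a mouse and the pool, and they were taken as log10 ratios. The log base is not given in the sources used here. The values are symmetric around 0 and end at exactly 2 and -2, which would be a 100-fold limit in log10. A fold printed in the text rests on that base, while p-values do not depend on it. The direction is likely mouse over pool, from the order of the samples in the titles, the dyes and the low Lpl values of the Lpl+/- mice. Scale and centring were left as deposited. Array medians lay between -0.0045 and 0.0072. There were no missing values, and 0 to 88 values per array stood at the limit. For arrays, the number of mice sets the precision.

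Of 120 pairs of arrays, 1 had a correlation over all probes under -0.3, wild type 5 with wild type 8 (r = -0.352). However, wild type 5 had r = 0.364 with wild type 4, and wild type 8 had r = 0.381 with wild type 7. Turning wild type 5 or wild type 8 alone would make its pair there at least as negative. The direction of these arrays is not settled by the values. The group fit, the main gene list test, the called genes around Lpl and the wild type background were repeated with either sign turned. The other tests were not repeated in this way. Among 128 patterns of signs of the wild type arrays, the deposited signs ranked 5 for bringing the wild type means close to 0.

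The array held 39556 probes. Of these, 23283 had 1 gene symbol in the platform annotation, 16273 had none and 0 had several. Probes of the same symbol were averaged, which left 36824 features, 20551 of them with a symbol. Symbols of 5952 features were updated through synonyms in a RefSeq gene table of assembly GRCm38.p6, and 19802 features were placed in gene order with it. The build behind the array is not given in the sources used here, so no coordinates are printed, and the table served for names, chromosomes and the order of neighbouring genes. A gene's place is counted in measured genes from Lpl, positive on one side and negative on the other.

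The groups were compared with limma (lmFit and eBayes, two-sided, version 3.58.1 in R 4.3.3) and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. A feature needed values on 6 arrays of each group, which every feature had. The fit had no block. Single genes and list means were also tested with an exact two-sided permutation test over all 12870 assignments of the mice. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. The 30 lists covered lipid, glucose and bile acid metabolism, inflammation, stress, time of day, sex-biased genes and markers of other cell types and tissues. They named 616 genes, 559 of them measured. Genes around Lpl were tested with Fisher's exact test on the 100 nearest measured genes, 50 on each side. The mean of the wild type arrays was tested against 0 as a background.

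The groups, tests, thresholds, lists and the main set of alternatives were fixed before the data were examined. The rule for naming genes was Lpl, then the 10 genes with the largest change in each direction among those past the threshold, filled up to 10 by the smallest p, and up to 4 members of each list described. Clone names without a gene symbol were not named. Alternatives covered centring, quantile normalization, single probes, filters, the variance model, array weights, the replicate numbers, thresholds, the pool as control, the size of the neighbourhood, camera settings and each mouse left out. Added after the data were seen were the turned signs, the values at the limit, the arrays with most of these, and a split of the mice by clock genes. The score of that split (Arntl minus the mean of Dbp and Per2) was chosen after the values of these genes had been seen, so the sign of Arntl alone was run beside it.

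The fits were tested on simulated arrays with the within-group SD of each of the 36824 features and a seeded set of features changed between Lpl+/- and wild type. Of features changed by 0.1 in log10, 55.2% were recovered, of those changed by 0.2, 86.6%, and of those changed by 0.3, 92.4%. These were 67, 67 and 66 features changed at once. The adjustment grows less strict with more changed features, so these rates are likely too high for the real comparison, which had 6 calls. Among the calls, 10 were unchanged features (6.02% of the calls). With nothing changed, 0 features were called. The simulation assumed independent normal features. Figures were drawn with matplotlib 3.10.9.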

Results

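Liver expression was measured in 8 Lpl+/- and 8 wild type male mice, each against a common pool of 9 wild type livers. Lpl encodes lipoprotein lipase, the enzyme that hydrolyses triglycerides of circulating lipoproteins. The comparison asked how the liver transcriptome of heterozygous mice differed from that of littermates. Values are log ratios of mouse over pool, a likely direction, taken as log10. The mice are separate animals, so the spread between them is biological and technical together.

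Lpl was lower in the Lpl+/- mice. The direction of the ratio was inferred in part from this gene, so its sign is not separate evidence. The mean log ratio was -0.387 ± 0.142 (SD, n = 8) in Lpl+/- and -0.00898 ± 0.0459 (SD, n = 8) in wild type livers, a difference of -0.378 or a fold of 0.419 (limma adjusted p = 0.0158). If the values were log2, the fold would be 0.769. The 8 Lpl+/- mice ranged from -0.573 to -0.208, all below the wild type range of -0.0622 to 0.0496, and the exact permutation p was 1.554e-04, the smallest that 12870 assignments can give. Whether the probe lies in the targeted part of the gene is not known. The adjusted p rose to 0.0526 without wild type 8 and to 0.0577 without Lpl+/- 2, and the call also ended with quantile normalization (limma adjusted p = 0.611) and with a robust, trended variance (limma adjusted p = 0.849). It ended too with the replicate block (limma adjusted p = 0.235), with the same 14 arrays without a block (limma adjusted p = 0.0523), without the 3 arrays with most values at the limit (limma adjusted p = 0.121) and in 1 of the sets of mice by clock genes (limma adjusted p = 0.271). In all, Lpl was called in 25 of 33 alternatives, over a range of 3.53e-04 to 0.849. The trended variance followed the mean absolute log ratio of each feature, which rises with a group difference itself. The loss of a call under it is thus partly built in. With the sign of wild type 5 or wild type 8 turned, the difference was -0.394 or -0.381 (limma adjusted p = 0.00955 and 0.0145).

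Of 36824 features, 6 differed between the groups, 3 higher and 3 lower in Lpl+/- livers, and all 6 were genes of chromosome 8, where Lpl lies. Ocel1, which encodes a protein with an occludin and ELL domain, was 2.20-fold higher (log ratio 0.345 ± 0.0419 against 0.00158 ± 0.0450, SD, n = 8 each, limma adjusted p = 6.93e-07). With quantile normalization its difference was 0.543 in place of 0.343 and no longer called (limma adjusted p = 0.611, over a range of 2.74e-07 to 0.849 across alternatives). Ints10, which encodes a subunit of the Integrator complex and is the gene next to Lpl, was 1.58-fold higher (limma adjusted p = 0.0356), and the zinc finger gene Zfp868 was 1.31-fold higher (limma adjusted p = 0.0165). Besides Lpl, the tropomyosin gene Tpm4 stood at 0.636-fold and Lsm4, which encodes a protein of the U6 small nuclear RNA particle, at 0.801-fold (limma adjusted p = 0.0356 each). In each of these genes the 8 Lpl+/- mice lay outside the wild type range, on the same side. Picking genes by p favours such a separation, so it is not separate evidence. It also held for Vps35 and Ccdc102a, which were not called (limma adjusted p = 0.572 and 0.314). On the array, Ocel1, Zfp868 and Ints10 carry older clone names. At an unadjusted p under 0.05 there were 2063 features (5.60%).

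**Figure D1:**
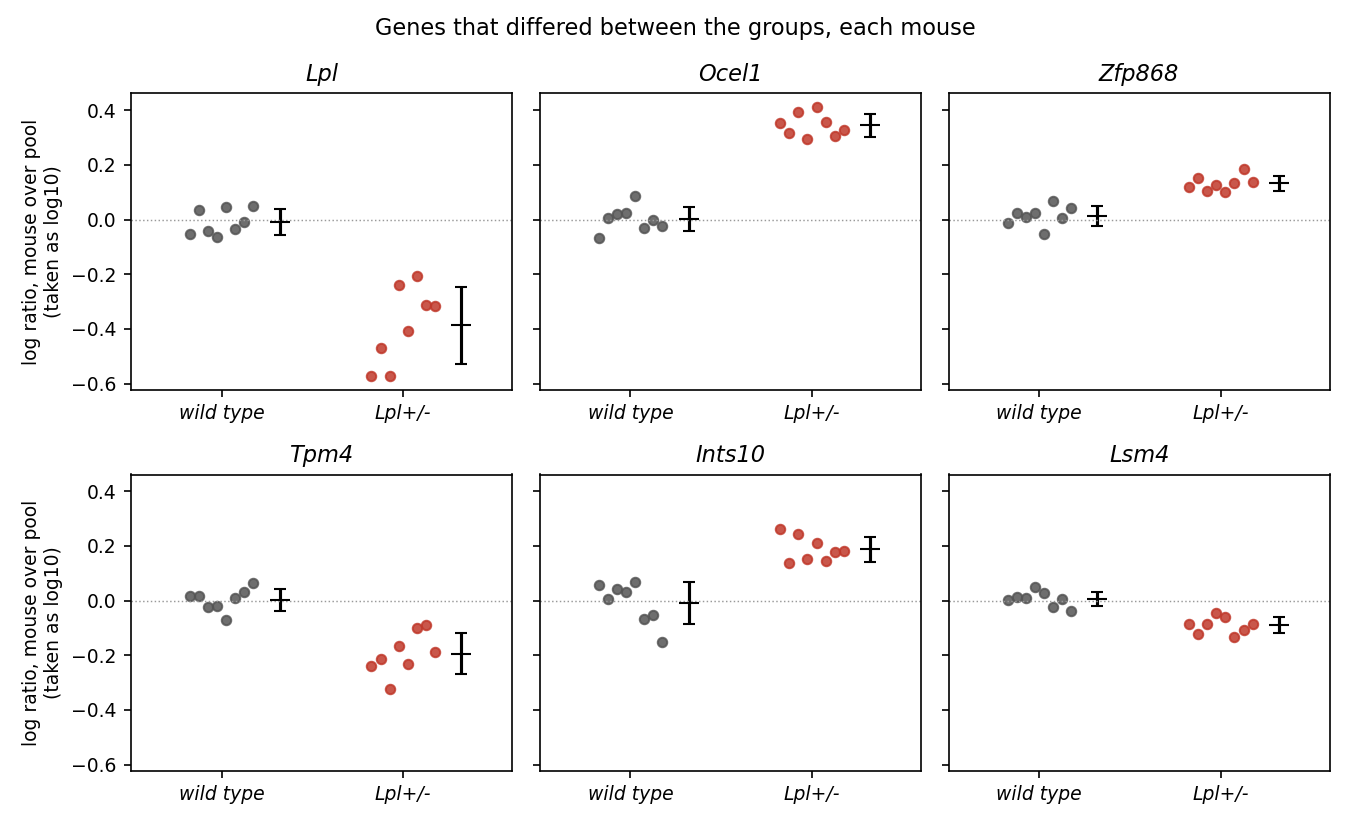
Log ratio of mouse over pool (taken as log10) for the 6 genes that differed, with 1 point per mouse, wild type in grey and Lpl+/- in red, and the mean and SD of 8 mice beside the points. Lpl lies between -0.573 and -0.208 in the Lpl+/- mice, and Ocel1 between 0.294 and 0.412.

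Of the 16 fits that left out 1 mouse, Ocel1 was called in 16, Lpl in 14, Zfp868 in 11, Tpm4 in 4, and Ints10 and Lsm4 in 2 each. The highest limma adjusted p was 0.115 for Ints10 and Tpm4 (without wild type 8), 0.124 for Lsm4 (without Lpl+/- 7) and 0.0613 for Zfp868 (without Lpl+/- 2). The count of 6 rose to 9 without wild type 6, 5 of them shared, with 3214 features at an unadjusted p under 0.05, and Slc18a1 was then called (limma adjusted p = 0.0250). It fell to 1 without wild type 8 or without Lpl+/- 2, and to 0 with quantile normalization or a robust, trended variance. It was 5 with the sign of wild type 5 turned and 3 with that of wild type 8 turned.

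The remaining genes named by rank did not pass the threshold. Among those higher in Lpl+/- livers, Rbl2, of the retinoblastoma family, was at 1.79-fold, Mylk3 at 1.47-fold, Csrp3 at 1.39-fold, the potassium channel gene Kcnn1 at 1.30-fold, the tRNA methyltransferase gene Trmt1 at 1.24-fold, Ano3 at 1.17-fold and the retromer gene Vps35 at 1.13-fold (limma adjusted p from 0.479 to 0.706). Among those lower, Slc18a1, the gene next to Lpl on the other side, was at 0.710-fold (limma adjusted p = 0.102), Cpne2 at 0.708-fold, Ccdc102a at 0.874-fold, Gatad2a at 0.800-fold, Rgs1 at 0.507-fold, Dlk1 at 0.881-fold, Nupl2 at 0.877-fold and Akr1b8 at 0.803-fold. Rbl2, Mylk3, Kcnn1, Trmt1, Vps35, Slc18a1, Cpne2, Ccdc102a and Gatad2a also lie on chromosome 8. Among placed genes of other chromosomes the lowest adjusted p was 0.479, and 0 were called (180 of 18837 at an unadjusted p under 0.01). Against the pool, without the wild type mice, 23 features were called in Lpl+/- mice, 11 on chromosome 8, 9 on other chromosomes and 3 without a place. The 9 were Tff3, Ehhadh, Cyp1a1, Nr4a1, Slc25a35, Dnajb4, Jun, Baiap2l1 and Csrp3, named after their values were seen, in a comparison that does not test the difference between the groups.

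Genes around Lpl differed between the groups more often than other genes. Of the 100 nearest measured genes, 3 were called (Ints10, Zfp868 and Lsm4), against 2 of 19701 others (Fisher's exact p = 1.24e-06). Fisher's test takes the genes as independent, so its p does not measure the spread between mice. At an unadjusted p under 0.01 there were 9 of these 100 genes, 5 higher and 4 lower, and 1.06% of the others. The difference was uneven along the chromosome in GRCm38.p6 gene order: 18 of the 100 genes on the side of Ocel1 and Tpm4 were at an unadjusted p under 0.01, against 4 of the 100 on the other side, where Ints10 lies, and 0.956% of genes on other chromosomes. On the side of Ocel1 and Tpm4, none of the 50 genes between 100 and 150 places away met that p. Of the 150 genes there beyond 150 and up to 300 places away, 10 did, 5 higher and 5 lower, including Trmt1, Vps35, Rbl2 and Cpne2. The count of 3 called neighbours fell to 0 without wild type 1, wild type 4, wild type 8, Lpl+/- 2 or Lpl+/- 8, while the count at an unadjusted p under 0.01 stayed between 8 and 11 when any 1 mouse was left out. With the sign of wild type 5 or wild type 8 turned, 2 or 1 of the neighbours were called (Fisher's exact p = 1.51e-04 and 0.0101).

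**Figure D2:**
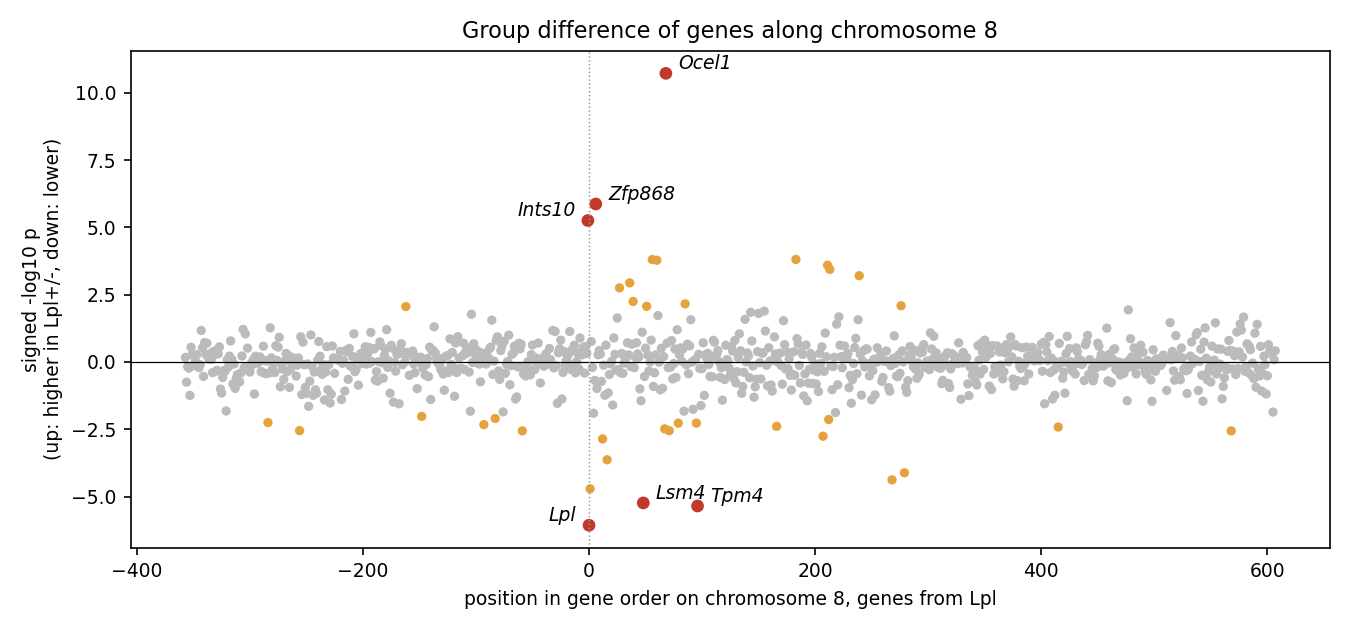
Each point is a measured gene of chromosome 8, placed by its order from Lpl (x axis, number of genes) and by -log10 of the unadjusted limma p with the sign of the group difference (y axis). Red points are the 6 called genes and orange points others at an unadjusted p under 0.01, and 18 red or orange points lie 1 to 100 genes from Lpl on the positive side.

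Genes of lipid metabolism other than Lpl did not pass the threshold. In the list of lipoprotein lipase and its partners, 1 of 18 measured members was called, Lpl itself. Of 30 lists, fry called 0 in 1 direction and 1 in mixed directions, this list (fry adjusted p = 4.09e-04), which was no longer called with Lpl taken out of it (fry adjusted p = 0.794). Pltp, which transfers phospholipids between lipoproteins, was at 0.741-fold and Cd36, a fatty acid transporter, at 1.32-fold (limma adjusted p = 0.836 each). Of 19 fatty acid synthesis genes 14 were lower and 5 higher in Lpl+/- livers, 0 past the threshold (camera adjusted p = 0.110), with Pnpla3 at 0.831-fold and Elovl6 at 0.796-fold. Cholesterol synthesis genes split 9 higher and 8 lower, with Insig1 at 0.831-fold. Genes of fatty acid oxidation and PPAR alpha targets split 12 higher and 14 lower, with Ehhadh at 0.669-fold and Ppara at 1.18-fold. Genes of triglyceride synthesis and lipid droplets split 13 higher and 11 lower, with Mogat1 at 1.30-fold, and those of glucose metabolism 8 higher and 9 lower, with G6pc at 0.811-fold. Among 20 genes of bile acid and sterol handling, Slco1b2, a bile acid transporter, was at 1.19-fold, past the threshold when adjusted over the list alone (limma adjusted p = 0.0402) but not over all features (limma adjusted p = 0.836).

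Immediate early genes, induced within minutes of a stimulus, were lower as a list in Lpl+/- livers (camera adjusted p = 0.00160), with 14 of 20 members lower. The call ended with an estimated correlation (adjusted p = 0.865), and the exact permutation p of the list mean was 0.0782. It also ended without Lpl+/- 3, wild type 4 and Lpl+/- 8, the 3 arrays with most values at the limit, where the list mean difference was -0.0437 in place of -0.0668 (camera adjusted p = 0.0698). The list mean lay between 0.0587 and 0.0996 in wild type 4, wild type 5 and wild type 6, but between -0.144 and -0.0517 in the other 5 wild type mice, within the Lpl+/- range of -0.155 to -0.0155. These 3 mice were singled out after their values were seen. With its sign turned, wild type 5 (0.0675 as deposited) would lie within the range of the other 5. Wild type 8 (-0.0546 as deposited), if turned, would lie outside it. No member passed over all features, and 1, Jun at 0.606-fold, passed when adjusted over the list alone (limma adjusted p = 0.0288). Nr4a1 was at 0.441-fold, with 0.180 to 0.474 in the same 3 wild type mice, -0.448 to -0.275 in the other 5 and -0.617 to -0.0822 in Lpl+/- mice. Here too, turning the sign of wild type 5 (0.327) or wild type 8 (-0.337) would move that mouse into the range of the opposite set. Atf3 was at 0.810-fold and Klf4 at 0.834-fold. Ribosomal protein genes were lower as a list too, 15 of 19 (camera adjusted p = 0.00554, adjusted p = 0.865 with an estimated correlation, exact permutation p = 0.149), by small amounts such as 0.906-fold for Rpl5 and 0.920-fold for Rps3. With the sign of wild type 8 turned, the ribosomal list was no longer called (camera adjusted p = 0.0715), and with that of wild type 5 turned 6 lists were called in place of 2. With an estimated correlation 0 of 30 lists were called.

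**Figure D3:**
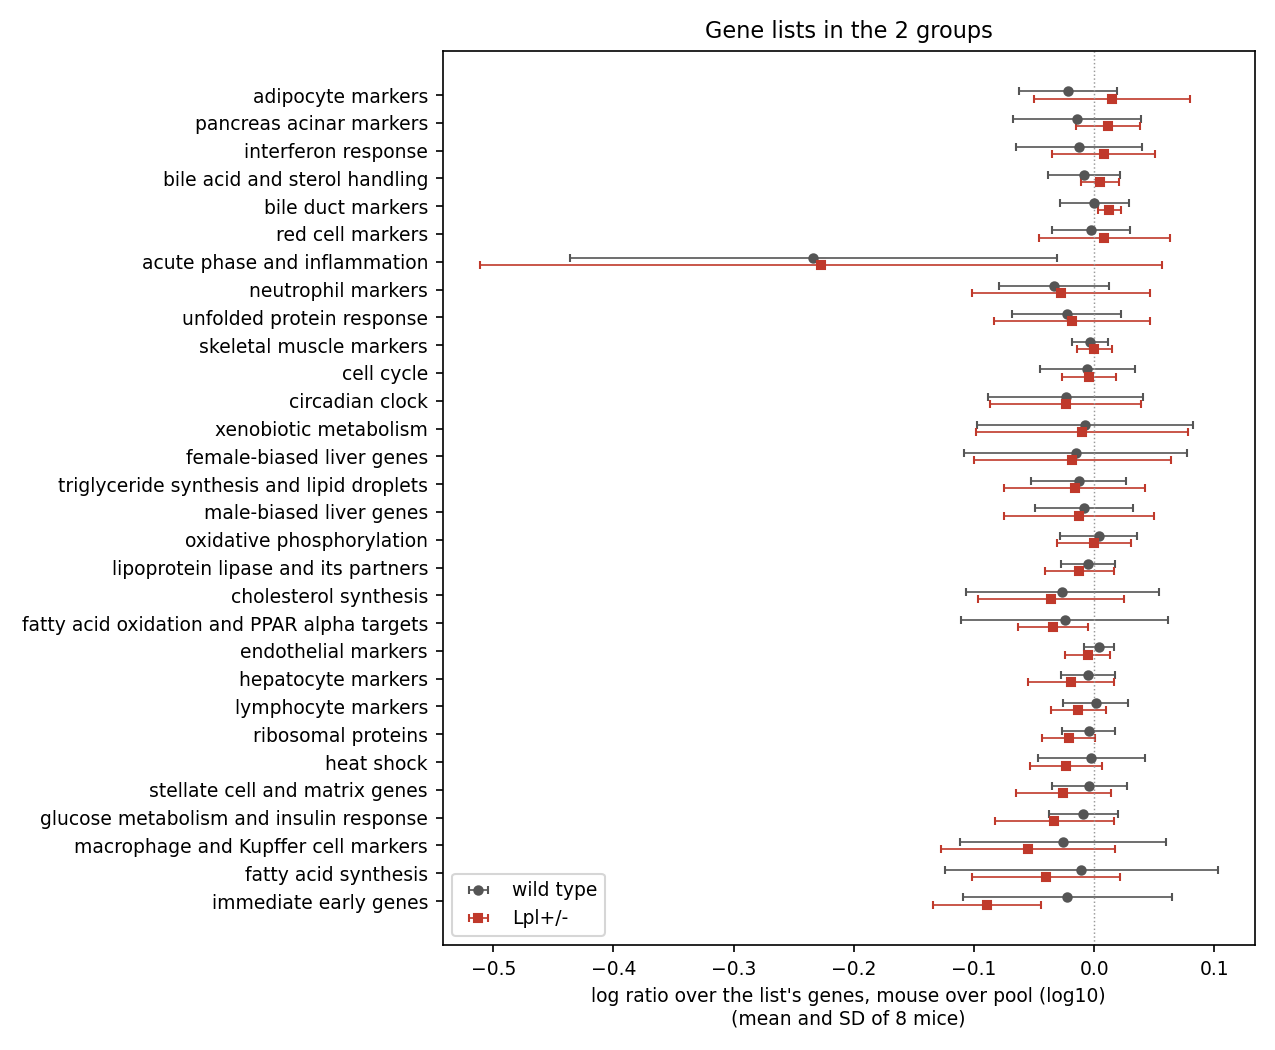
Mean log ratio over the genes of each of 30 lists (x axis, mouse over pool, taken as log10), with points at the mean and bars at the SD of 8 mice, wild type in grey circles and Lpl+/- in red squares. The bars of the groups overlap in all 30 lists, and the acute phase list has the widest bars.

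Markers of other liver cell types did not pass the threshold at the preset correlation, but several lists did under alternatives. Stellate cell and matrix genes had 15 of 22 members lower (camera adjusted p = 0.0547), with Lrat at 0.861-fold, and macrophage and Kupffer cell markers 22 of 26 (camera adjusted p = 0.102), with Csf1r at 0.847-fold. Interferon response genes had 16 of 22 members higher (camera adjusted p = 0.110), with Ifit1 at 1.30-fold, and adipocyte markers 8 of 11 (camera adjusted p = 0.153). Heat shock genes had 11 of 16 members lower (camera adjusted p = 0.0719), with Hspa4 at 0.855-fold. In the remaining lists the camera adjusted p lay at 0.508 or above. These held lymphocyte, neutrophil, endothelial, bile duct, hepatocyte, red cell, pancreas acinar and skeletal muscle markers, acute phase, cell cycle, xenobiotic, sex-biased, clock, unfolded protein and oxidative phosphorylation genes. Among them, the neutrophil gene Ngp was at 0.844-fold, past the threshold when adjusted over the list alone (limma adjusted p = 0.0429). Of 33 alternatives, stellate cell and matrix genes were called in 13, macrophage and Kupffer cell markers in 12, heat shock genes in 10, fatty acid synthesis genes in 8, interferon response genes in 6, acute phase genes in 2 and lymphocyte markers in 1. The camera adjusted p ranged from 7.15e-04 to 0.977 for stellate cell genes and from 1.22e-06 to 0.977 for macrophage markers. These lists are therefore left open.

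The mice also fell into sets by their clock genes within both groups, 7 mice with low Arntl against Dbp and Per2 (4 wild type, 3 Lpl+/-) and 9 with the opposite (4 wild type, 5 Lpl+/-). These sets were defined from the data after the values were seen, and Lpl+/- 4 changes sides if the sign of Arntl alone is used. Wild type 5 and wild type 8 would each change sides if its own sign were turned. Within these sets the Lpl difference was -0.508 (limma adjusted p = 0.0456) and -0.308 (limma adjusted p = 0.271), Ocel1 differed by 0.359 and 0.331, and 1 and 0 features were called. Immediate early genes differed by a list mean of -0.0973 and -0.0373, and ribosomal genes by -0.0277 and -0.0136. At the preset correlation 4 lists were called in the low set, these both included, and 1 other list in the high set. With an estimated correlation 0 lists were called in either set (camera adjusted p = 0.865 in the low and 0.779 in the high set for both lists). With the set as a block and the preset correlation, 5 features and 5 lists were called, and with the sign of Arntl alone as a block 6 features and 3 lists.

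No feature was called between wild type mice and the wild type pool (limma, 0 called, 691 at an unadjusted p under 0.05), and turning the sign of wild type 5 or wild type 8 left 0 called (442 and 1268 at an unadjusted p under 0.05). Without wild type 5, 1 feature was called. Whether these wild type mice were among the 9 of the pool is not known. If they were, a mean near 0 was partly fixed in advance, and the low counts say little about background.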

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

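The slope test of wild type 6 was chosen after its values were seen. In 292 groups of 8 mice, 2 for each of 146 named genes, 1 mouse stood far from the other 7 in 25. With normal values, chance gives about 14.6. Some clock and acute phase genes among the 146 were added after their values were seen, and genes can move together in 1 mouse. The excess is therefore not a test.

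Wild type 6 stood apart for Mylk3 (0.177, next mouse 0.0085) and wild type 9 for Cpne2 (0.168, next mouse 0.0323), both genes of chromosome 8 more than 200 measured genes from Lpl. For each mouse the slope of its values on the group difference, fitted without that mouse, was taken over the genes 150 to 300 places away that were at an unadjusted p under 0.01 in that fit. It was 1.08 in wild type 6, between -0.562 and 0.0655 in the other wild type mice, and between 0.652 and 1.58 in the Lpl+/- mice. Without Mylk3, which led to the test, it was 1.06 in wild type 6, at most 0.0946 in the other wild type mice and at least 0.667 in the Lpl+/- mice. Without Rbl2 as well it was 0.963 in wild type 6 and at most 0.208 in the other wild type mice. Of the 12 genes, wild type 6 lay more than midway to the Lpl+/- mean in 10. It did not in Vps35 (-0.0062, Lpl+/- mean 0.0474) or Ccdc102a (0.0635, Lpl+/- mean -0.0393). Neither of these 2 genes was called between the groups, so either could be in the set by chance. Whether they break a stretch of donor DNA is left open. Over such genes among Ints10 and the 100 nearest on the other side of Lpl, the slope of wild type 6 was 0.337, between the other wild type mice (-0.218 to 0.135) and the Lpl+/- mice (0.775 to 1.18). Vps35, 211 places from Lpl, lay between Dhps (207) and Orc6 (212), in both of which wild type 6 went with the Lpl+/- mice. No such slope was taken over genes of other chromosomes, so whether the resemblance is limited to chromosome 8 is not known. Over all probes wild type 6 had r = 0.493 with Lpl+/- 5, the highest of the 120 pairs of arrays. With the other Lpl+/- mice its r lay between -0.128 and 0.301. A candidate explanation is donor strain DNA in wild type 6 on part or all of the far stretch, and how far it would reach towards Lpl is left open. The strains are not given in the sources used here and no genotype was measured, so this is a hypothesis from the same data.

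Lpl+/- 4 was apart for the acute phase genes Lcn2 (0.915) and Orm2 (0.944), and for Car3 (-0.411), Cyp3a25 (-0.296), Cyp1a1 (-0.210), Cyp2d9 (-0.152) and Baat (-0.161). Lpl+/- 6 was apart for Pnpla3 (0.0347), G6pc (0.0598), Csf1r (0.129), Il1b (0.180), Ptprc (0.161), Ngp (-0.125) and Nr4a1 (-0.0822). Wild type 1 was apart for Fads2 (0.152) and Ahsg (-0.169), wild type 4 for Idi1 (-0.312) and wild type 5 for Cyp1a1 (0.487), Cux2 (-0.128) and Atf3 (0.173). Wild type 8 was apart for Car3 (-0.407), wild type 9 for Cd4 (0.0931) and Lpl+/- 3 for Sult2a1 (-0.297).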

How the results depend on the processing

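Alternatives chosen after seeing the data were the turned signs, the values at the limit, the 14 arrays without a block, the clock gene sets, the list without Lpl, and for the neighbours of Lpl every alternative except the size of the neighbourhood. The 6 called features became 4 with centred arrays, 7 with array weights and 5 without the less variable features, and both filters on missing values removed nothing and test nothing. Quantile normalization gave 0 features, 0 called neighbours of Lpl, 4 lists and an Lpl difference of -0.432. Robust, trended variance gave 0 features with Lpl at -0.378. Its trend followed the mean absolute log ratio, not spot brightness, and so works against features that differ between the groups. Pairing of the mice by replicate number was not shown and not excluded: of 7 shared numbers 3 had correlated deviations over 0.1 (median r 0.0583) and 1 was the best match of its mouse. The replicate block gave 1 feature, 0 neighbours, 6 lists and Lpl at -0.343 (limma adjusted p = 0.235), and the same 14 arrays without the block 1 feature, 0 neighbours, 5 lists and Lpl at -0.343 (limma adjusted p = 0.0523), so the smaller set of mice alone gave the same counts of features and neighbours. An adjusted p under 0.01 kept 1 feature, and an unadjusted p under 0.01 took 393. Lpl+/- mice against the pool gave 23 features, 6 of them shared. With the sign of wild type 8 turned 3 features were called, and with that of wild type 5 turned 6 lists. Without the 3 arrays with most values at the limit (Lpl+/- 3, wild type 4, Lpl+/- 8), 1 feature, 0 neighbours and 1 list (ribosomal) were called, with Lpl at -0.364 (limma adjusted p = 0.121). Array weights gave 5 lists, ranks 4 and an estimated correlation 0. With clock gene sets as a block 5 lists were called, and with the sign of Arntl alone as a block 6 features and 3 lists. Low Arntl mice alone gave 1 feature, 0 neighbours and 4 lists, and the others 0 features, 0 neighbours, 1 list and Lpl at -0.308, with 0 lists in either set at an estimated correlation. Leaving out 1 mouse gave 1 to 9 features: 9 without wild type 6, 1 without wild type 8 or Lpl+/- 2, 2 without wild type 1, wild type 4 or Lpl+/- 8, and 3 without wild type 2, 5 or 7 or Lpl+/- 1 or 5. It gave an Lpl difference of -0.404 to -0.352, 0 to 3 neighbours, 0 to 1 feature against the pool (1 without wild type 5), and 2 to 7 lists: 4 without wild type 2, 5 or 7 or Lpl+/- 3 or 6, 5 without wild type 4, 6 without Lpl+/- 4 and 7 without wild type 9. Where not stated, the cause was not tested. The 5 called genes other than Lpl lost the call in 85 of 165 repeats: of 33 each, Ocel1 was called in 29, Zfp868 in 21, Tpm4 in 13, Ints10 in 10 and Lsm4 in 7, and Lpl in 25. Named genes that were not called gained a call in 6 of 4365 repeats between the groups, and 0 reversed. A reversal needed a call in the main fit or in the repeat, so sign changes without a call were not counted. Against the pool, which these repeats leave out, 9 of the named genes not called between the groups were called. Spot brightness was not used here, so what signal over background limits is unknown.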

Other observations

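The splits of the mice and the clock gene test were planned before their results were seen, and the tests of gene order around Lpl were chosen after. The clock genes, the acute phase genes and the sets of mice named here were picked after their values were seen.

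Acute phase genes varied more between mice than between groups. Saa1, which encodes serum amyloid A, ranged from -1.60 to 0.0273 in wild type and from -1.43 to 0.513 in Lpl+/- livers. It lay below the pool in 7 of 8 mice of each group. The ends of the wild type range were wild type 5 and wild type 8, so turning either sign would change this range and the wild type count. Saa3 ranged from -1.64 to 0.0153 and from -1.44 to 0.794, and Orm2 lay below the pool in all 8 wild type and in 7 Lpl+/- mice. The same wild type mice were the ends for Saa3, and with either sign turned Orm2 would lie below the pool in fewer wild type mice. With the signs as deposited, Lpl+/- 4 had the highest value of Saa1, Saa3, Orm2, Mt2 (0.821) and Lcn2 (0.915). The next Lpl+/- mouse lay at -0.0669 for Saa1 and -0.195 for Saa3. With the sign of wild type 5 turned, wild type 5 would lie above Lpl+/- 4 for Saa1, Saa3, Orm2 and Mt2, but not for Lcn2. The estimated correlation among the list's genes, 0.613, was the highest of the 30 lists.

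All 6 called features lie on chromosome 8. Of 100 splits of the 16 mice into 8 and 8, the real one included, 1 gave as many called features (6, highest of the others 1). Likewise 1 gave as many of the 100 neighbours of Lpl at an unadjusted p under 0.01 (9, highest of the others 7). Both counts were thus rare among the splits. Chance is an unlikely origin of either, but 100 splits cannot exclude it, and the margin was narrower for the neighbours. An effect of the targeted allele on the 5 nearest genes of each side alone would not cover the 4 called genes that lie farther away. That limit of 5 was set after their places had been seen, and Zfp868 lies 6 places away. An effect of the allele with a longer reach was not tested. The Fisher tests that follow take genes as independent and do not measure the spread between mice. Of 95 genes 6 to 100 places away on one side, 17 were at an unadjusted p under 0.01 (Fisher's exact p = 1.23e-16 against other chromosomes), against 3 of the 95 on the other side (Fisher's exact p = 0.0646, adjusted p = 0.0922), or 4 of 100 there with the 5 nearest genes (Fisher's exact p = 0.0164, adjusted p = 0.0411). The first is consistent with donor strain DNA linked to the targeted allele, a hypothesis since the strains are not given, and why the other side held fewer was not tested. Whether probes bind the donor allele less well cannot be told apart from a change of expression: 10 of the 22 genes concerned were higher in Lpl+/- mice, and which strain the probes match is unknown.

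Of the same 100 splits, 93 gave at least 2 called gene lists (highest 14), so chance cannot be excluded for the lower immediate early and ribosomal lists. The preset correlation of the test was 0.01, while estimated correlations reached 0.613, and 0 lists were called with an estimated correlation.

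Clock genes parted the mice within both groups. The score of Arntl minus the mean of Dbp and Per2 was at most -0.417 in 7 mice and at least 0.0906 in the other 9. The low scores belonged to wild type mice numbered up to 5 and Lpl+/- mice numbered up to 3, and the high scores to those numbered from 6 and from 4. This holds for the signs as deposited. With its sign turned, wild type 5 would join the high scores. Wild type 8, if turned, would join the low scores and break the order. Of 14 other clock genes, 12 (85.7%) had a correlation with Arntl of the sign that their known phase requires. It was weak for Npas2 (r = 0.178) and at least 0.408 in size for the other 11, and Cry1 (r = -0.0648) and Nr1d1 (r = 0.124) were the exceptions. This argues against array noise, although arrays of the low set held more values at the limit (189 against 60). A candidate explanation is a different time of day of collection, which the same 12 of 14 genes bear on. Feeding time and other batches were not tested. Lpl+/- 4 falls in the low set by the sign of Arntl alone.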
